A study of Gallus gallus with 2 samples.

How the data were processed

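Single-cell RNA-seq was made from pectoralis muscle, the breast fillet, of commercial chickens (Gallus gallus). The labels describe 2 samples, 1 from healthy birds (normal) and 1 from birds with wooden breast. Per the labels' protocols, muscle was digested with collagenase I (0.15 g per 100 mL) for 30 min, passed through a 40 µm strainer and cleared of dead cells with magnetic beads. Lipid cells were left out, and 8000 cells were the capture target. The labels name a 10x Genomics 3' kit of version 3 and the series' design text names version 2, so the kit version is open. Shares of cells describe this suspension and not the tissue.

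The deposited values are UMI counts per gene and cell barcode, whole numbers without normalization, per the file headers. Cell Ranger 4.0.0 wrote the matrix per the file headers, while the submitters' processing notes name Cell Ranger 3.1.0. The genome build, the annotation and whether sequencing depth was equalised when libraries were joined are not given in the sources used here. Genes carry Ensembl chicken identifiers and, for 12461 of 16779, a symbol. No coordinates are printed because the files give none. For 18 symbols carried by more than 1 gene the UMIs were summed, which concerns CCL4 among the named genes.

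The matrix joins 6 libraries, told apart by a number from 1 to 6 at the end of each barcode. Neither the labels nor the files say which number is normal and which is wooden breast muscle, or how many birds stand behind a number. The numbers were not assigned to a group. The planned ratios of wooden breast over normal muscle were therefore not computed, and each library is given as its own value or as a range and median over the 6. The libraries are not replicates of a group. No test across them was made and no p-value is given.

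The matrix held 55117 barcodes and 115269653 UMIs, between 7221 and 11388 barcodes per library against the target of 8000 cells. Total UMIs per library ran from 15890116 to 25390489. Barcodes with under 200 detected genes (993) or over 20% of UMIs in the 13 mitochondrial protein genes (19154, or 34.8%) were removed, which left 35944. Scrublet (scanpy 1.11.5, run per library) marked 154 of these (0.428%), of which 127 lay in library 6. A caller that marks under 0.5% of cells has not worked. The marked barcodes were removed as planned, but doublets remain in all classes. The 35790 kept cells held a median of 1331 UMIs and 597 genes, and 39.2% of them had under 1000 UMIs.

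UMIs were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were standardised with values limited to 10 SD, and 30 principal components were computed (numpy 2.4.6). Cells were linked to 15 nearest neighbours (scikit-learn 1.9.0) and clustered with the Leiden method (leidenalg 0.10.2, resolution 0.5). Mitochondrial, ribosomal protein and haemoglobin genes and every member of the 19 gene lists were left out of these features, so that the levels of list members were not fixed by the clustering. Each cluster was scored with marker lists fixed before the data were examined, as the mean log2 fold of detected markers over the median cluster with 10 CPM added. It took the best list's name where the score was at least 2.4, led the next list by at least 1.0 and had at least 3 markers at 2-fold. These 3 limits were set after the clusters had been seen. Names therefore carry the ending "-like". No separate annotation of cells was used.

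For each class, UMIs were summed over its cells and given as CPM, the count scaled to a total of 1e6, with exact Poisson 95% intervals. Shares of cells have exact Clopper-Pearson 95% intervals, and ratios of CPM have exact conditional binomial 95% intervals (scipy 1.17.1). All intervals cover counting error only: cells are not replicates, and differences between birds are not in them. A member of a list was measured with at least 20 UMIs. It was called for its highest class where the ratio to the second-highest class was at least 1.5, the interval lay above 1 and the class was highest in at least 5 libraries. Only classes with at least 10 cells in a library were compared there. Muscle fibre-like cells, with enough cells in 3 libraries, and Schwann-like cells, with enough in 1, therefore could not give a call. The named genes were fixed by rule before the data were examined: in each list the 3 members with the highest CPM in any class, plus the member with the largest ratio of highest to second-highest class among those with at least 100 UMIs. Tests on simulated data used 5499 candidate genes and 2 classes. There the interval lay on the right side of 1 for all 94 genes changed 2-fold and all 106 genes changed 4-fold, up or down. Of the intervals of unchanged genes, 94.8% held the true ratio. The rule for calls was not part of these tests. Cluster naming placed 1200 of 1200 simulated cells in the right one of 4 classes. Those cells had the markers of their own class raised and those of the others lowered, at equal depth, without free RNA or doublets. These tests check the interval and naming steps and do not tell how well the names hold in these data.

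Alternatives fixed before the data were examined changed the gene minimum, the mitochondrial limit, the doublet step, the Leiden resolution, the number of variable genes, the feature rule, the summary over cells, the depth per cell and the library size, and took each library on its own. Removing the mitochondrial limit, removing the 6% of cells with the highest Scrublet scores and leaving clusters unnamed whose 10 leading genes held more markers of another list than of their own were added after the data had been seen.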

Results

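The study set out to describe the cell types and their gene expression in wooden breast, a myopathy of fast-growing broilers in which the breast muscle hardens, beside normal breast muscle. The deposited matrix pooled 6 numbered libraries that neither labels nor files tie to normal or wooden breast muscle. The data therefore answer which cells were recovered and which classes carried which genes, over all libraries together, and each library's values are given as those of an unassigned library. Of 55117 barcodes, 35790 were kept as cells. Kept cells per library numbered between 4703 (library 3) and 7273 (library 6), with median depths between 942 UMIs (library 2) and 2005 UMIs (library 6).

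Red blood cells, which are nucleated in birds, and lymphocytes made up most of the cells kept under the main filters. They did not with a minimum of 500 genes (erythroid-like 8.17%, T-or-NK-like 33.8%) or without a mitochondrial limit (23.8% and 22.9%). Erythroid-like cells, with haemoglobin HBBA at 143793 CPM, took 34.6% of kept cells (95% interval 34.1 to 35.0), and T-or-NK-like cells took 24.1% (23.6 to 24.5). That share was 23.2% without cluster 16, whose 307 cells had 0 T-or-NK markers and 1 B marker (BLK) among their 10 leading genes. The T-or-NK-like cells carried the cytotoxic granule gene GNLY at 9174 CPM and the T-cell receptor component CD3D at 1996 CPM. Mural-like cells (the smooth muscle cells and pericytes of vessels, with MYH11, TAGLN and RGS5) took 9.04%, endothelial-like cells (PECAM1, VWF) 6.40%, and fibroblast-like cells (DCN, LUM) 5.91%. Cluster 7, with the macrophage markers C1QC and LY86, took 4.63%. It is called macrophage-like by its score, 4.13 against 2.41 for the heterophil list, although its 10 leading genes held 2 heterophil markers (RSFR, EXFABP) and 1 macrophage marker, so that heterophils are not excluded from it. Satellite-like cells, with the myogenic regulators PAX7 and MYOD1, took 3.42%. B-like cells, led by the antibody joining chain JCHAIN at 53467 CPM, took 0.810%, muscle fibre-like cells 0.517% and Schwann-like cells 0.129%. The remaining 10.5% of cells lay in 4 clusters that matched no single marker list.

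The libraries differed far beyond counting error in these shares. Erythroid-like cells ranged from 16.6% in library 6 to 58.6% in library 2, with a median of 34.3%, and T-or-NK-like cells from 10.3% in library 2 to 46.4% in library 4, with a median of 19.6%. Macrophage-like cells ranged from 1.04% (library 3) to 14.2% (library 5), and mural-like cells from 4.18% (library 6) to 16.3% (library 3). Satellite-like cells varied least among the larger classes, from 2.45% to 4.32% of kept cells. This sums 2 clusters that varied more, cluster 13 from 0.402% to 4.22% and cluster 14 from 0.054% to 3.11%. Of cells other than erythroid-like, the satellite-like share ran from 3.47% to 8.65%. Unnamed cells took between 2.94% (library 2) and 21.5% (library 6). The filters set part of these values: the erythroid-like share fell to 8.17% with a minimum of 500 detected genes, and the endothelial-like share was 2.50% with a mitochondrial limit of 10% and 19.4% without a limit. With 500 genes the mural-like share was 14.1% and the fibroblast-like share 8.93%, and with the 10% limit the macrophage-like share was 2.86%. The clustering also moved classes. Without a mitochondrial limit, a setting chosen after seeing the data, the mural-like share was 3.80%. The cells kept then rose from 35790 to 53970, and 1566 of the 3234 mural-like cells, 1510 of them from cluster 9, lay in unnamed clusters. Values for mural-like cells without that limit therefore describe mainly cells of cluster 8. Of the smaller classes, satellite-like cells took 1.77% at a Leiden resolution of 1.0 and 0.598% with 4000 variable genes, B-like cells 2.24% and 1.42% in these settings and 2.28% with 500 genes, and Schwann-like cells 0.911% at a resolution of 1.0.

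**Figure D1:**
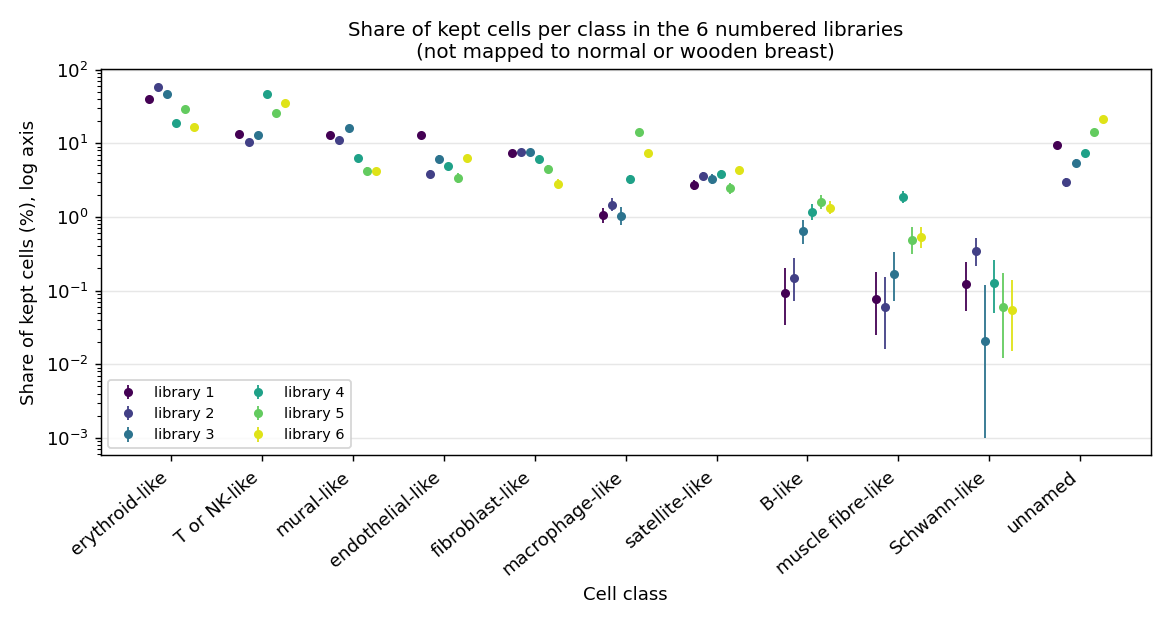
Share of kept cells (percent, log axis) in each cell class, with 1 point per numbered library and exact 95% binomial intervals (counting error only). T-or-NK-like cells run from 10.3% to 46.4% and erythroid-like cells from 16.6% to 58.6%. Satellite-like cells, the sum of 2 clusters that each vary more, stay between 2.45% and 4.32%.

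Fibroblast-like cells carried most of the extracellular matrix genes. Of 21 measured collagens and matrix genes, 15 were highest in them and 13 of these were called. COL1A1 (ENSGALG00000041555), a chain of type I collagen, stood at 26619 CPM (26511 to 26726) in fibroblast-like cells and at 5942 CPM in satellite-like cells, the next class, a ratio of 4.48 (4.44 to 4.52) with fibroblast-like cells highest in 6 of 6 libraries. COL3A1 (ENSGALG00000035584) reached 22980 CPM with a ratio of 4.03 to satellite-like cells. The matricellular gene POSTN (ENSGALG00000017046) reached 8676 CPM, 9.88 times the level in satellite-like cells, and SPARC 8927 CPM, 2.50 times that in mural-like cells. The size of these ratios depended on which satellite-like cells were compared. COL1A1 in satellite-like cells ranged from 578 CPM in library 3 to 14154 CPM in library 4, where different clusters held most of them, and its ratio from 2.49 to 44.8. With a minimum of 500 genes and at a Leiden resolution of 1.0 the ratio was 36.2 and 38.5 for COL1A1, 9.95 and 13.9 for COL3A1 and 76.5 and 36.3 for POSTN. Across the libraries COL1A1 in fibroblast-like cells ranged from 10027 to 38399 CPM and POSTN from 3107 to 13733 CPM.

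Of 13 measured collagen processing genes, 10 were highest in fibroblast-like cells and 7 of these were called. The collagen chaperone SERPINH1 stood at 1451 CPM, 1.82 times its level in satellite-like cells, and the prolyl hydroxylase subunit P4HA3 at 275 CPM with a ratio of 5.40. With 500 genes and at a resolution of 1.0 these ratios were 3.98 and 4.76 for SERPINH1 and 47.3 and 26.1 for P4HA3. PLOD1, a lysyl hydroxylase, was at 338 CPM against 288 CPM in satellite-like cells and was not called. PCOLCE2, which enhances procollagen cleavage, was at 39.0 CPM, but between 3.71 and 71.2 CPM by library. Matrix proteases and inhibitors were spread over more classes, with 5 of 14 highest in fibroblast-like cells, 4 of them called. MMP2 (1895 CPM, ratio 3.33) and TIMP2 (1725 CPM, ratio 2.08) were highest there, whereas TIMP3 was highest in mural-like cells (2605 CPM, 3.99 times endothelial-like cells) and MMP7 in macrophage-like cells (375 CPM, 16.4 times satellite-like cells). MMP7 in macrophage-like cells ranged from 15.8 CPM in library 3 to 1246 CPM in library 4. Its ratio to satellite-like cells ran from 1.32 to 311 in single libraries, and was 692 with 500 genes, 1075 at a resolution of 1.0 and 10.6 without a mitochondrial limit. The MMP2 ratio was 6.09 at a resolution of 1.0 and the TIMP3 ratio 6.74 without a mitochondrial limit.

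Among 18 TGF-beta and BMP signalling genes, 8 were highest in fibroblast-like cells, 4 of them called. With a minimum of 500 genes, and with the mean of each cell's CPM, the count fell to 5. THBS1, an activator of latent TGF-beta, reached 1644 CPM there, 3.63 times mural-like cells, and the activin and myostatin antagonist FST 414 CPM, 14.8 times (7.15 to 36.7) Schwann-like cells, where it had 7 UMIs. The FST ratio was 5.03 with 500 genes and 7.57 with Scrublet calls kept, and the THBS1 ratio 11.1 without a mitochondrial limit. TGFB2 was highest in satellite-like cells, at 596 CPM against 449 CPM in fibroblast-like cells, in only 3 of 6 libraries, and was not called. This order turned with 500 genes and at a resolution of 1.0. Growth factors and receptors had 5 of 17 members highest in fibroblast-like cells, 3 of them called, and 3 members highest there with a minimum of 500 genes. PDGFD was called for fibroblast-like cells (505 CPM, ratio 2.92), HBEGF for mural-like cells (584 CPM) and MET, the receptor of hepatocyte growth factor, for satellite-like cells (93.6 CPM, ratio 4.60, 5 of 6 libraries). The pooled HBEGF ratio of 2.16 to muscle fibre-like cells lay below the 10.3 and 22.8 of the 2 libraries that gave one, and was 9.87 with the mean of each cell's CPM and 5.06 with each cell thinned to 1000 UMIs. The PDGFD ratio was 5.38 without a mitochondrial limit and the MET ratio 7.35 with 500 genes. PDGFA was highest in satellite-like cells at 320 CPM, 1.48 times Schwann-like cells over all libraries, 12.8 times in the only library where both could be compared and 3.61 times at a resolution of 1.0. Of 6 measured complement genes, 3 were highest in fibroblast-like cells and all 3 were called. C7 was at 529 CPM with a ratio of 12.6 to mural-like cells (3.002 to 48.2 in single libraries and 47.3 without a mitochondrial limit) and C1S at 412 CPM with a ratio of 5.13 to satellite-like cells. CFD was called for endothelial-like cells, at 673 CPM.

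Endothelial-like cells led the angiogenesis list, with 9 of 15 members highest and 8 of these called. The Notch ligand DLL4 (ENSGALG00000008514) stood at 159 CPM, 70.9 times (48.4 to 108) the next class. ENG, a TGF-beta co-receptor of endothelium, was at 348 CPM with a ratio of 9.57 to mural-like cells, NOTCH1 at 520 CPM with a ratio of 2.29 and NRP1 at 473 CPM with a ratio of 2.54. Each of these 4 genes was highest in endothelial-like cells in 6 of 6 libraries. Without a mitochondrial limit the ratio was 38.0 for DLL4, 17.1 for ENG and 1.57 for NRP1. The DLL4 ratio was 118 with 500 genes and 110 after thinning, and the ENG ratio 5.89 with the mean of each cell's CPM. Immediate early genes, which cell dissociation is known to induce, were high in the vessel classes, with 6 of 13 members highest in mural-like cells and 4 in endothelial-like cells. BTG2 (6565 CPM, ratio 2.44) and SOCS3 (2485 CPM, ratio 2.85) were called for mural-like cells. FOS at 19718 CPM in mural-like cells and JUN at 18272 CPM in endothelial-like cells were not called, with ratios of 1.36 and 1.09 between these classes. The FOS ratio was 2.06 without a mitochondrial limit. FOS in mural-like cells ranged from 8187 CPM (library 6) to 24482 CPM (library 2).

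Macrophage-like cells led the lysosome and phagocyte list, with 16 of 18 members highest and 10 of these called. The protease CTSS was at 1895 CPM, 13.5 times Schwann-like cells (21.1 with 500 genes and 20.6 at a resolution of 1.0), and GRN at 1627 CPM, 5.30 times B-like cells, while LAMP1 at 1274 CPM was close to the 1163 CPM of erythroid-like cells and was not called. No separate cluster was named heterophil-like. With clusters 7 and 16 left unnamed, a setting chosen after seeing the data, fibroblast-like cells led this list with 7 members. Of 18 cytokine and chemokine genes 6 were highest in macrophage-like cells, 4 of them called. IL1B, a central inflammatory cytokine, stood at 3463 CPM (3416 to 3510), 29.8 times (20.6 to 44.8) the next class in 6 of 6 libraries (53.7 times with the 6% highest Scrublet scores removed), and CCL4, the sum of 2 genes of that symbol, at 6949 CPM, 6.48 times T-or-NK-like cells. Unnamed cluster 6, left out of these comparisons, had a gene of the CCL4 symbol at 38.5-fold over the other clusters. The 10 leading genes of cluster 7, down to 26.5-fold, did not hold CCL4. The highest CCL4 level therefore need not lie in macrophage-like cells. CXCL14 was called for fibroblast-like cells at 128 CPM, with a library range of 46.2 to 302 CPM. CCL21 was highest in the 46 Schwann-like cells at 1675 CPM, but fibroblast-like cells, at 416 CPM over all libraries, came next and the order did not hold in the only library that could be evaluated. At a Leiden resolution of 1.0, where a dendritic-like class of 372 cells was named, that class led with 6 members and the macrophage-like count fell from 6 to 3. With a minimum of 500 genes dendritic-like cells led with 7 against 4.

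Lipid uptake and storage genes had 6 of 16 members highest in macrophage-like cells, 4 of them called, such as ACSL1 (329 CPM). The pooled ACSL1 ratio of 9.99 to fibroblast-like cells lay above the 1.23 to 8.73 of the single libraries. The fatty acid binding protein FABP5 was called for endothelial-like cells at 3008 CPM, 3.98 times macrophage-like cells, and FABP4, at 1943 CPM in mural-like and 1697 CPM in macrophage-like cells, was not called and turned to a ratio of 0.518 without a mitochondrial limit. APOA1 (ENSGALG00000007114), the main protein of high-density lipoprotein, was the most abundant gene named in fibroblast-like cells. It stood at 100207 CPM there, 3.16 times satellite-like cells, between 56990 and 176216 CPM by library. This ratio ran from 1.375 to 26.4 in single libraries, and was 9.17 with 500 genes and 12.8 at a resolution of 1.0. Leukocyte adhesion genes were split, with 2 of 5 each highest in T-or-NK-like and in macrophage-like cells. SPP1 (456 CPM, ratio 24.9) and ITGB2 (483 CPM, ratio 1.89) were called for macrophage-like cells, and CD44 at 1063 CPM in T-or-NK-like cells was not called. The SPP1 ratio to satellite-like cells ran from 1.94 to 175 in single libraries, and was 121 with 500 genes and 48.4 at a resolution of 1.0.

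B-like cells led the chaperone and unfolded protein response list, with 5 of 14 members highest and 4 of these called. The class was cluster 17, led by JCHAIN, TXNDC5 and FKBP11 and with 3 B markers at 2-fold. Cluster 11, with a B score of 3.004, stayed unnamed, so these levels need not hold for all B cells. The endoplasmic reticulum chaperone HSP90B1 was at 6040 CPM, 3.05 times satellite-like cells, and the disulfide isomerase PDIA4 at 1550 CPM, 5.28 times fibroblast-like cells, both in 5 of 5 libraries with enough B-like cells. With 500 genes and at a resolution of 1.0, where more cells were named B-like, the ratio was 1.60 and 1.499 for HSP90B1, the latter below the 1.5 needed for a call, and 3.24 and 2.68 for PDIA4. The cytosolic chaperones HSPA8 and HSP90AA1 were nearly level in mural-like (13267 and 21351 CPM) and T-or-NK-like cells (12561 and 19716 CPM) and were not called.

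Antigen presentation genes were highest in macrophage-like cells for 4 of 8 members, 1 of them called. BLB2, a class II beta chain, was at 8872 CPM there, 3.42 times endothelial-like cells, and CD74, the class II invariant chain, at 10984 CPM with a ratio of 1.84, in 4 of 6 libraries. B2M, the light chain of class I molecules, was called for erythroid-like cells at 34388 CPM, 2.12 times Schwann-like cells (4.49 with 500 genes and 3.83 at a resolution of 1.0). No member was highest in macrophage-like cells at a Leiden resolution of 1.0 or with a minimum of 500 genes, where a dendritic-like class was named and led with 5 members.

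Interferon response genes were highest in erythroid-like cells for 6 of 11 members, 4 of them called. IFIT5 stood at 1735 CPM and RSAD2 at 318 CPM, 5.08 times T-or-NK-like cells, each in 6 of 6 libraries with a wide range (IFIT5 from 582 to 6048 CPM). The pooled IFIT5 ratio of 2.31 to muscle fibre-like cells, most of which came from library 4, lay below the 5.01 to 12.04 of the single libraries. IRF1, at 1141 CPM in mural-like cells, was within 1.19 times of erythroid-like cells and was not called. IFI6 was at 1977 CPM in muscle fibre-like and 1730 CPM in erythroid-like cells over all libraries, but it was lower in fibre-like cells in each of the 3 libraries with at least 10 of them (3195 against 8751 CPM in library 4) and was not called. The erythroid-like count fell to 1 in each of the 4 settings that named a small thrombocyte-like class and were run on this list, and IFIT5 was no longer higher in erythroid-like than in muscle fibre-like cells when each cell was thinned to 1000 UMIs. Antioxidant genes had 4 of 18 members highest in erythroid-like and 4 in macrophage-like cells, and 2 highest in erythroid-like cells with a minimum of 500 genes. HMOX1, which breaks down haem, was called for macrophage-like cells at 1030 CPM, 9.92 times the next class (36.5 with the 6% highest Scrublet scores removed, 16.7 without a mitochondrial limit and 15.3 with the mean of each cell's CPM), and MT4, a metallothionein, for mural-like cells at 1616 CPM. The ferritin chain FTH1 at 45460 CPM in erythroid-like and 33770 CPM in macrophage-like cells, and TXN at 2438 CPM in satellite-like cells, were not called. TXN was higher in B-like than in satellite-like cells with 500 genes.

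Muscle fibre-like cells were few (185, of which 104 came from library 4), and the preparation was not made to recover whole fibres. They led the slow muscle and fibre stress list with 9 of 12 members highest. As they are the only fibre class, this lead does not tell slow from other fibres. By fold over the other clusters their leading genes were MYL1 (500), TNNI2 (375), TNNC2 (335) and TNNT3 (294), ahead of TNNC1 (252). TNNC1, the slow troponin C, was at 12205 CPM, 215 times (192 to 241) the next class. The cardiac actin ACTC1, also expressed in developing fibres, was at 6738 CPM and the stress-induced ANKRD1 at 1649 CPM, 20.1 and 11.96 times satellite-like cells. At a resolution of 1.0 these ratios were 7.52 and 6.55, the ACTC1 ratio was 31.1 after thinning, and the TNNC1 ratio was 129 without a mitochondrial limit. Each order held in 3 of 3 libraries with enough fibre-like cells. Of 12 glycolysis and hypoxia genes 3 each were highest in macrophage-like, mural-like and muscle fibre-like cells, and muscle fibre-like cells led with 4 under the mean of each cell's CPM. The glycolytic enzymes GAPDH (60893 CPM) and LDHA (5047 CPM), highest in muscle fibre-like cells, stood at 12.9 and 5.14 times macrophage-like cells. ENO1 at 1618 CPM in macrophage-like cells was not called.

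Cell cycle genes had 6 of 17 members highest in T-or-NK-like cells, none of them called. The topoisomerase TOP2A was at 114 CPM there and 86.2 CPM in B-like cells. The T-or-NK-like level averages over 4 clusters. In cluster 15, 474 of these cells, 5 list members were among the 10 leading genes by fold over the other clusters. They were TOP2A (14.2), UBE2C (13.8), HMGB2 (10.1), CENPF (9.72) and CDK1 (9.71). HMGB2 was at 211 CPM in satellite-like cells, and BIRC5 (329 CPM) and PCNA (377 CPM) were highest in the 46 Schwann-like cells, which also carried the red-cell anion exchanger SLC4A1 at 677 CPM. With 500 genes and at a resolution of 1.0 the T-or-NK-like count was 0, B-like cells led with 16 and 15 members, and TOP2A stood in T-or-NK-like cells at 0.425 and 0.474 times its level in B-like cells. With 500 genes BIRC5 and PCNA in Schwann-like cells were at 0.228 and 0.653 times T-or-NK-like cells. HMGB2 was higher in T-or-NK-like than in satellite-like cells with 500 genes, at a resolution of 1.0, without a mitochondrial limit and with list members allowed as clustering features. In the last setting the T-or-NK-like count was 15.

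**Figure D2:**
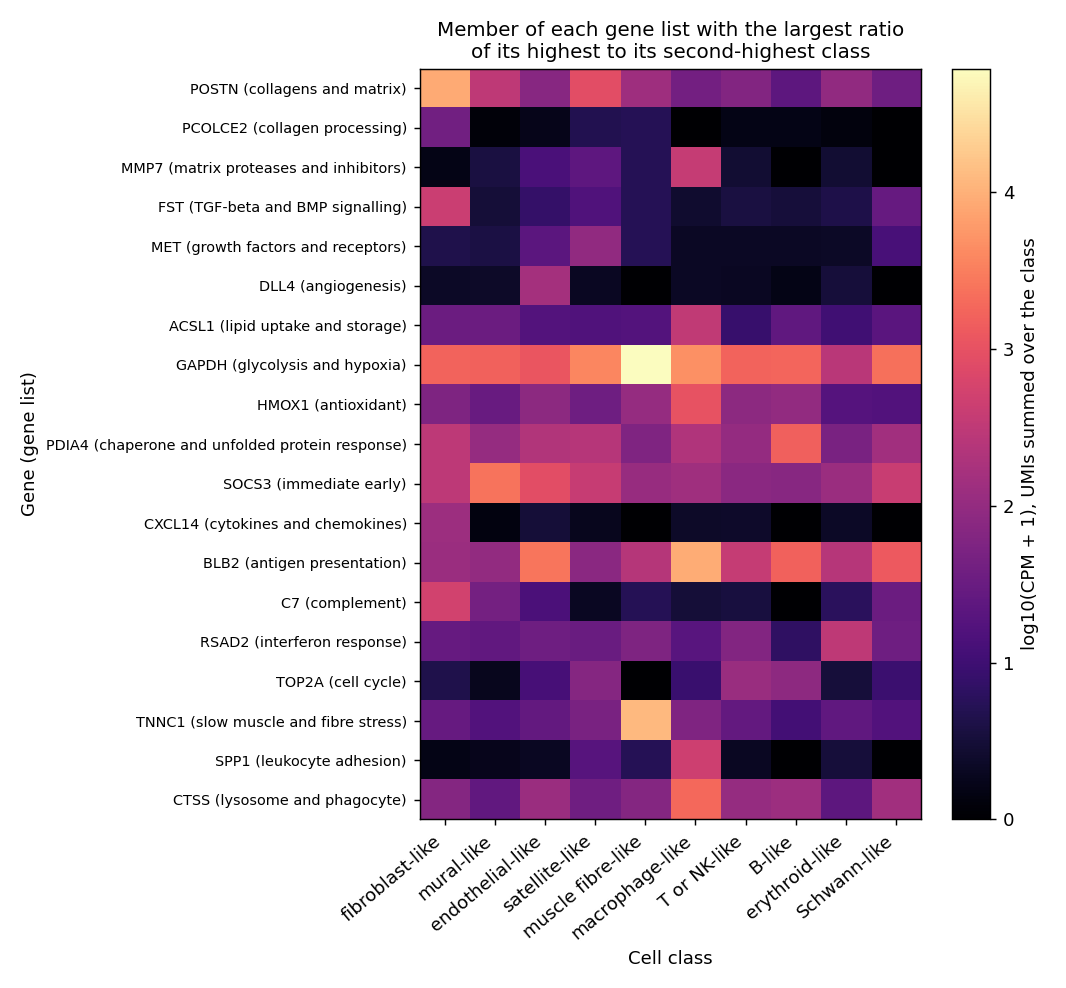
Level of 19 genes, 1 per gene list, in the 10 named cell classes, as log10 of CPM plus 1 from UMIs summed over all kept cells of a class. DLL4 stands out in endothelial-like cells (159 CPM), POSTN in fibroblast-like cells (8676 CPM) and TNNC1 in muscle fibre-like cells (12205 CPM).

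UMIs of abundant genes were also seen in classes that should lack them. HBA1 was seen in 97.6% of erythroid-like cells (median depth 738 UMIs) and in 26.9% of T-or-NK-like cells (1563 UMIs), where it stood at 3254 CPM against 111808 CPM. COL1A1 was seen in 99.3% of fibroblast-like cells (3699 UMIs) and in 27.6% of T-or-NK-like cells, at 182 CPM. Of the HBA1 UMIs in T-or-NK-like cells, 95.6% lay in 234 cells with at least 10 each, whereas cells with at least 10 COL1A1 UMIs held 4.81% of the COL1A1 UMIs there. Free RNA and remaining doublets were not separated, and low levels of these genes outside their own class were not read as expression. A comparison of wooden breast with normal muscle was not made for any class or gene.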

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

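All tests here were chosen after the data had been seen. Over all libraries, and in each of libraries 1 to 3, endothelial-like cells were the largest class among the barcodes that the mitochondrial limit, fixed beforehand, removed. In libraries 4 to 6 T-or-NK-like cells were the largest (33.6%, 38.1% and 30.4%, against 25.1%, 22.9% and 23.1% for endothelial-like cells). When all barcodes with at least 200 genes were clustered without the limit, 8420 of the 18180 barcodes above 20% mitochondrial UMIs (46.3%, 45.6 to 47.0) grouped with endothelial-like cells. They made up 80.3% of that class, whose median mitochondrial share was 37.7%, against 13.4% in T-or-NK-like and 1.14% in erythroid-like cells. Above the limit these barcodes held a median of 1562 UMIs. Without the limit the endothelial-like share was 27.6%, 26.2%, 29.9%, 11.4%, 8.48% and 9.24% in libraries 1 to 6. These barcodes are outside the main comparisons and enter only the values given without the limit. Whether these are damaged cells or cells rich in mitochondria was not tested.

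The 4 unnamed clusters hold signal that no list comparison uses. Cluster 6 held 1736 cells, of which 1076 came from library 6, 391 from library 5, 249 from library 4 and 13, 3 and 4 from libraries 1 to 3. Its leading genes by fold were BATF3, CCLL4, CCL4, NCF1C and CA9, and its best list, macrophage, scored only 1.63. Cluster 10 held 899 cells, 451 from library 1, with endothelial markers (score 3.74) and mural markers (3.05) together. Cluster 11 held 883 cells with B (3.004) and dendritic (2.75) markers, and at a Leiden resolution of 1.0 a dendritic-like class of 372 cells was named. Cluster 18 held 247 cells led by HDC, the histamine-forming enzyme, and GATA2, and scored 2.26 for T or NK, under the limit of 2.4 set after the clusters had been seen. Its share per library ran from 0.197% (library 4) to 1.69% (library 5).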

How the results depend on the processing

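Over the settings other than single libraries, 170 of 184 counts of list members stayed within 1.5 times, 44 of 92 class shares stayed inside their counting intervals, and of 632 log2 ratios of named genes 305 stayed inside their intervals, 326 moved and 1 called gene turned. Counting genes that were not called, 28 of these ratios turned in sign, and 41 of 69 genes moved by over 1.5 times in at least 1 setting. In single libraries, the lowest of 69 ratios stayed inside its interval for 4 genes and was negative for 19, and the highest stayed inside for 3. Of 60 ratios with at least 2 such libraries, the pooled value lay outside their range for 4 (HBEGF, ACSL1, IFIT5 and IFI6). Unless stated, the cause was not tested. No paired analysis was possible because no library is mapped to a group. The 6 alternatives for ratios of wooden breast over normal muscle were not run for the same reason. Depth limits shallow classes most: thinning left 3305 of 12366 erythroid-like and 78 of 185 muscle fibre-like cells, against 275 of 290 B-like cells. No Schwann-like class was found in 5 settings and no muscle fibre-like class with a minimum of 500 genes, so these gave no values there.

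With a minimum of 500 genes 21151 cells were kept, since shallow cells were removed, and 53970 without a mitochondrial limit. With 500 genes the named, T-or-NK-like, endothelial-like and erythroid-like shares were 87.8%, 33.8%, 8.58% and 8.17%. With a 10% mitochondrial limit they were 88.9%, 17.5%, 2.50% and 47.4%, and without a limit, chosen after seeing the data, 86.0%, 22.9%, 19.4% and 23.8%. At resolution 1.0 the named, endothelial-like and erythroid-like shares were 88.7%, 5.64% and 33.4%, and with 4000 variable genes the named and endothelial-like shares were 88.7% and 6.02%. With Scrublet calls kept the endothelial-like share was 6.10%. With clusters 7 and 16 left unnamed, added later because markers of another list outnumbered their own among their 10 leading genes, the named and T-or-NK-like shares were 84.0% and 23.2%, 14 of 14 list counts of the other classes stayed within 1.5 times, and the 5 lists led by macrophage-like cells gave no count. With the 6% highest scores removed, also added later, T-or-NK-like, endothelial-like and erythroid-like shares were 24.6%, 6.08% and 35.2%.

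Counts of list members highest in their main class moved in these cases. TGF-beta and BMP signalling in fibroblast-like cells had 5 with 500 genes and 5 with the mean of each cell's CPM. Growth factors and receptors had 3 with 500 genes and up to 9 in a single library. Antioxidant genes in erythroid-like cells had 2 with 500 genes and up to 7 in a single library. Cytokines and chemokines in macrophage-like cells had 3 at resolution 1.0. Antigen presentation in macrophage-like cells had 0 with 500 genes, 0 at resolution 1.0 and 0 in the lowest library. Interferon response in erythroid-like cells had 1 with 500 genes, 1 with list members as features, 1 without a mitochondrial limit and 1 with the highest Scrublet scores removed, where thrombocyte-like cells took 10, 9, 8 and 9 members. Cell cycle in T-or-NK-like cells had 0 with 500 genes, 0 at resolution 1.0, 15 with list members as features, and from 0 to 16 in single libraries. In single libraries, glycolysis and hypoxia in macrophage-like cells reached 5, and the lowest counts were 3 for immediate early genes in mural-like cells, 0 for leukocyte adhesion in T-or-NK-like cells and 10 for lysosome and phagocyte genes in macrophage-like cells.

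Of called genes, IFIT5 had a log2 ratio of -0.012 for erythroid-like over muscle fibre-like cells after thinning. In the lowest single library PCOLCE2 (fibroblast-like over muscle fibre-like, the only library with UMIs in both) was at -0.90, MET (satellite-like over endothelial-like) at -0.015, MT4 (mural-like over macrophage-like) at -1.04 and BLB2 (macrophage-like over endothelial-like) at -0.21.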

Other observations

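All tests in this part except 2, which are named below, were chosen after the results had been seen. The satellite-like class was made of 2 clusters with different programmes. Cluster 14 carried PAX7 at 562 CPM, MYF5 at 297 CPM and CDH15 at 348 CPM, and cluster 13 carried these at 182, 58.4 and 181 CPM. MYOG, which marks differentiating myoblasts, had 762 UMIs (126 CPM) in cluster 13 and 0 UMIs in cluster 14. Of the matrix genes, which were not used for the clustering, FN1 stood at 5750 CPM in cluster 13 and 63.7 CPM in cluster 14 (ratio 90.3, 75.9 to 108), TNC at 1524 and 79.3 CPM, COL1A1 at 7656 and 708 CPM and TGFB2 at 746 and 139 CPM. COL4A1 (413 and 2800 CPM), LTBP2 (190 and 768 CPM) and BMP4 (13.6 and 370 CPM) went the other way. Of 20 measured collagens and matrix genes, 8 were over 1.5 times as high in cluster 13 and 4 in cluster 14 with the whole interval past that limit. Of 17 measured TGF-beta and BMP signalling genes, 3 were higher in cluster 13 and 7 in cluster 14 by the same limit. Of libraries 1 to 6, cluster 13 took 26, 32, 25, 212, 76 and 307 cells and cluster 14 took 151, 207, 128, 3, 49 and 7. Levels per cluster may thus be levels of libraries. At a Leiden resolution of 1.0 the satellite-like share was 1.77% against 3.42%, and which of these cells lost the name was not traced. The COL1A1 ratio of fibroblast-like over satellite-like cells was then 38.5 against 4.48. The TGFB2 ratio of satellite-like over fibroblast-like cells was 0.306 against 1.33. Both moved towards the levels of cluster 14, so the class need not hold the same 2 clusters in that setting.

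The T-or-NK-like share of cells other than erythroid-like fell into separate ranges, with 22.1%, 24.8% and 24.1% in libraries 1 to 3 and 57.0%, 36.5% and 42.0% in libraries 4 to 6. The mural-like share of kept cells was 13.1%, 11.2%, 16.3%, 6.33%, 4.22% and 4.18% in the same order. Over all kept cells the highest T-or-NK-like share was 4.52 times the lowest, and with erythroid-like cells left out 2.57 times, so leaving them out removed part of the spread, and dilution by red blood cells was not the whole reason. Removing the mitochondrial limit did not reduce the spread, since without the limit the ratio among cells other than erythroid-like was 3.22 against 2.57. Naming of shallow cells was tested with a bound written before its result was seen, and among cells with at least 1000 UMIs the ratio was 2.56. The difference between wooden breast and normal muscle cannot be told apart from differences between birds or preparations, because 0 libraries are mapped to a group.

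Interferon response genes stood apart in library 4. Of 86 pairs of a list member and a class, 77 were highest in library 4 and 5 in library 2, and the median pair stood in library 4 at 4.84 times its median over the libraries. IFI6 in satellite-like cells was at 22.1, 1245, 44.6, 5555, 144 and 195 CPM in libraries 1 to 6, and MX1 in fibroblast-like cells at 5.49, 97.5, 24.7, 454, 13.3 and 30.3 CPM. IRF1 did not follow in 5 of 8 classes, such as mural-like cells with 626 CPM in library 4 and 1681 CPM in library 1. Free RNA from the erythroid-like cells, some of which formed a cluster led by CMPK2 and RSAD2 with 451 of 841 cells from library 4 and 310 from library 2, would keep the ratio of these genes to HBA1, but in the other classes of library 4 the median ratio was 47.7 times that in erythroid-like cells. That ratio used all UMIs of library 4 and not only the excess, so a member's own level also raises it. IRF1 in mural-like cells reached 180 times although library 4 was at 0.68 times its median. The test therefore speaks only for pairs far above their median, where most UMIs are excess. IFI6 in satellite-like cells, at 32.8 times its median, was at 67.5 times. The lowest pair, IFIT5 in T-or-NK-like cells at 6.71 times its median, was at 4.01 times. A library size without mitochondrial, ribosomal protein and haemoglobin genes, a test whose bound was written before its result was seen, left the median pair at 4.57 times. An interferon response of the birds behind library 4 is a hypothesis that stays open, and so does a difference between the groups, since 0 libraries are mapped to a group.

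ADIPOQ, a hormone gene of fat cells, led mural-like cluster 9 at 4951 CPM, beside RGS5 and KCNJ8, which mark pericytes, while mural-like cluster 8, with MYH11 at 7151 CPM, held 708 CPM. Cells were then taken by their RGS5 and KCNJ8 UMIs, without the cluster labels. Both genes were among the leading genes of cluster 9 with ADIPOQ, so a higher share was known beforehand. The shares restate the cluster's levels per cell and are not a separate check. At 1000 UMIs per cell 87.2% (84.9 to 89.3) of 933 cells with both had an ADIPOQ UMI, against 4.38% of 17531 cells with neither, with 14018 shallower cells left out. With all UMIs the shares were 92.8% and 5.82%. Free RNA would give like shares, and the ratio was 19.9. Doublets with fat cells would leave most such cells without ADIPOQ. The fat-cell genes PLIN1 and CIDEC had 2 and 0 UMIs in cluster 9. They reached at most 1.68 and 2.99 CPM in any cluster, so these low counts cannot speak against fat-cell RNA. CIDEA, another fat-cell gene, had 68 UMIs (15.7 CPM) in cluster 9, and FABP4 was at 4402 CPM there. Expression of ADIPOQ by pericyte-like cells is a hypothesis. The design gives no biological contrast for it, so no biological explanation was tested.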
